A study of Sus scrofa with 6 samples.

How the data were processed

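Gene expression was measured by sequencing of total RNA from the subcutaneous fat of pigs of a Duroc, Landrace and Yorkshire cross. Per the labels, 3 libraries came from animals on a control diet and 3 from animals on a diet with 400 mg/kg resveratrol, a plant polyphenol. RNA was extracted with Trizol and prepared with a long non-coding RNA (lncRNA) kit, per the labels' protocols. The labels also name a small RNA kit, and small RNA was not analysed here. Groups and replicate numbers were taken from the sample titles. The labels do not state that the samples of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

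The authors deposited 1 table per library with a whole-number read count and a TPM value (a transcript abundance scaled for length and library total) for each of 22844 rows, per the file headers. Of these rows, 22452 carry pig Ensembl gene identifiers and 392 are assembled loci with the prefix MSTRG and no Ensembl gene. A deposited table of the whole series holds TPM for 14777 rows, which are exactly the rows with at least 1 TPM in at least 1 library. Its values differed from those of the library tables by at most 0 TPM. Per the submitters' processing notes, Bowtie 0.12.2 and the mouse builds mm8 and mm9 were used. The rows carry pig identifiers, so the pig build and annotation behind these counts are not given in the sources used here, and no coordinates are printed. The counting program and its handling of strand are likewise not given, so reads of overlapping or antisense genes and of close paralogs cannot be assigned with certainty.

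Library totals ran from 16251536 reads in control 2 to 37943877 reads in resveratrol 2. Symbols were taken from a table that pairs gene identifiers with symbols, and 14750 of the 22844 rows matched. The tables give no RNA class. Matching symbols to RefSeq classes gave no usable lncRNA set, so the assembled loci are reported as a group of their own and stand in for the planned lncRNA comparison. They are not all shown to be non-coding. The planned test of each lncRNA against its neighbouring gene needs coordinates and was not run.

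The planned main test was limma on log2 TPM. Because the deposited tables hold counts, edgeR 4.0.16 was used in its place, as the plan provided for. Rows with a mean of at least 0.5 TPM over the 6 libraries were kept, which left 14908 rows, 11431 of them with a symbol, and 381 assembled loci. Counts were scaled by TMM (trimmed mean of M values) and tested with the robust quasi-likelihood test, with Benjamini-Hochberg adjustment over all tested rows and a threshold of 0.05. The standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic. Fold changes are resveratrol against control. The biological coefficient of variation was 0.235. Levels are the deposited TPM values as mean ± SD of 3 libraries per group. Counts and TPM of a gene can differ in direction. TPM also depends on the transcript length the authors assigned, and it is not scaled by TMM. In limma on log2(TPM + 0.5) the median log2 fold change over all tested rows was -0.079, against -0.0075 in edgeR. Against the TMM-scaled counts, TPM thus lay lower in resveratrol relative to control. This bears on the TPM levels, on counts of genes whose groups do not overlap, and on list medians from limma on log2 TPM. R 4.3.3, limma 3.58.1 and DESeq2 1.42.0 were also used.

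Before the data were examined, 35 gene lists were fixed for adipocyte metabolism, signalling and the cell types that fat can hold. The 30 lists with at least 5 tested members were tested with camera (limma) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and adjusted over the lists. Camera with an estimated correlation and fry, one-way and mixed, were alternatives. The text names genes by a rule also fixed beforehand. It takes 12 genes with a symbol per direction that pass the adjusted threshold with non-overlapping libraries, filled by the smallest unadjusted p where fewer pass, and 4 assembled loci per direction by the same order. It adds 4 members of each called list, up to 2 of each other list, and 13 genes of fat metabolism named in any case. No gene passed in edgeR, the main test, so every gene named under the first part is a fill. A few genes that the rule takes are not reported here. Genes outside the rule are said to be chosen after their values were seen.

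Alternatives were limma on log2(TPM + 0.5), log2(TPM + 1) and log2(TPM + 0.1), limma without trend and robust, with array weights and on quantile-normalized values, other filters on low values, removal of the top 20 genes and the mitochondrial genes, the rows of the series table, DESeq2, a fit with the replicate number as a block, and each library left out in turn. Chosen after seeing the data were limma with the pseudocount of 0.5 as an alternative, DESeq2 size factors in edgeR, library totals alone, edgeR without robust, the set test of the assembled loci and DESeq2 with each library left out. Other splits of the 6 libraries into 3 and 3, 10 in all, were refitted. No 2 libraries agreed within sampling noise, with a chi-square per degree of freedom from 61.5 to 233 over the pairs. The tests were first tested on simulated data with the real means and library sizes. The changed genes were drawn from rows with a mean of at least 1 CPM. Genes were simulated independently and without outlying libraries, so the recovery does not describe every tested row. Of genes changed 1.5-fold, 8.96% of 67 were recovered, of those changed 2-fold 46.3% of 67, and of those changed 4-fold 89.4% of 66. Beside these 6, 31 and 59 genes, 10 of 14688 unchanged genes were called.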

Results

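Subcutaneous fat of pigs on a control diet was compared with that of pigs on a diet with 400 mg/kg resveratrol, with 3 libraries in each group. Depth was 31528317, 16251536 and 34048559 reads in control 1, 2 and 3 and 34653702, 37943877 and 34436239 reads in resveratrol 1, 2 and 3, so that control 2 was the shallowest library. Between 18078 and 18686 rows had at least 1 read in a library. A pair of assembled loci took a large part of each library, the first by TPM and the second by reads. MSTRG.12981 held 16.6% to 25.8% of all TPM but only 1.498% (control 3) to 2.42% (control 1) of the reads. MSTRG.14710 held 6.92% of the reads in control 2 and 17.6% in control 3, but 2.13% and 5.74% of their TPM. The first principal component (33.6% of variance) set control 2 apart, and the second (26.6%) spread control 1 and resveratrol 3 to opposite ends.

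**Figure D1:**
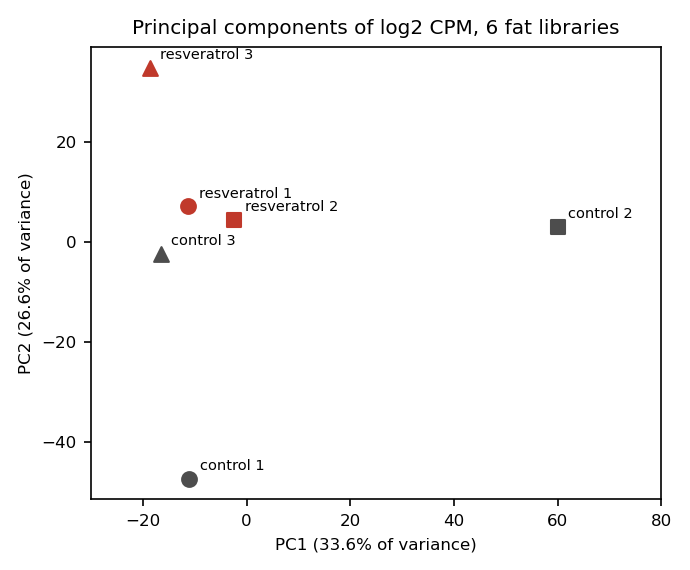
Principal components of log2 CPM over the tested genes, 1 point per library, with control in grey and resveratrol in red and the share of variance on each axis. Control 2 lies at 59.98 on PC1, and the other 5 libraries lie below 0.

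The first comparison asked which genes differed between the diets. With camera's preset correlation, the lists of circadian clock, immediate early and mitochondrially encoded genes were called lower in resveratrol, and those of macrophages and of neutrophils and mast cells were called higher. With an estimated correlation none of these lists was called (adjusted p = 0.770 for each), and fry without a replicate block called 0. The immediate early call was lost without control 1 or resveratrol 3, and the neutrophil and mast cell call without control 2 or resveratrol 1. No member of these lists passed the adjusted threshold by itself in edgeR on all 6 libraries. NR1D1 (ENSSSCG00000036933.1), the nuclear receptor that represses BMAL1, averaged 3.58 ± 0.923 TPM in control and 1.31 ± 0.299 TPM in resveratrol (SD, n = 3 each). HSPA5 (ENSSSCG00000005601.3), the chaperone of the endoplasmic reticulum, averaged 129 ± 23.2 against 195 ± 14.5 TPM.

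Of 14908 genes tested, edgeR's quasi-likelihood test called 0 at an adjusted p under 0.05, and the smallest Benjamini-Hochberg adjusted p was 0.409. At an unadjusted p under 0.05 there were 973 genes (6.53%, where chance gives 5%), 329 higher and 644 lower in resveratrol, and 3 other splits of the libraries into 3 and 3 gave more, from 1016 to 1082. DESeq2 on the same counts called 40 genes, 8 higher and 32 lower, and all 40 had an unadjusted p under 0.05 in edgeR. The DESeq2 count went from 19 without resveratrol 3 to 197 without control 2, and the latter shared 35 genes with the 40. In edgeR, 5 genes passed without control 2. Groups did not overlap in 1827 genes (12.3%, where chance gives 10%). A fold change of at least 2 together with an unadjusted p under 0.05 was met by 205 genes, 51 higher and 154 lower. Quantile normalization gave 36 higher and 64 lower. Without control 3 there were 59 higher and 264 lower at that fold change, and the 973 became 1681. The 973 became 556 without resveratrol 1 and 403 without resveratrol 3.

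Among the genes with the smallest unadjusted p in the lower direction, none passing the adjusted threshold in edgeR on all 6 libraries, RFX2 (ENSSSCG00000035403.1), a transcription factor of ciliated cells, had a log2 fold change of -1.27 (SE 0.19). It averaged 4.52 ± 0.307 TPM in control and 1.83 ± 0.349 TPM in resveratrol, and edgeR's adjusted p was 0.409. SFRP2, a secreted Wnt modulator, had a log2 fold change of -1.88 (SE 0.36), and GLI3, a transcription factor of Hedgehog signalling, one of -1.07 (SE 0.22). HOXA10, a homeobox gene of posterior body identity, measured 9.18, 2.31 and 6.82 TPM in control 1, 2 and 3 and 1.05, 1.24 and 0.072 TPM in resveratrol 1, 2 and 3. FCN2, a lectin of the complement system, averaged 143 ± 17.8 against 71.6 ± 8.63 TPM. FSCN1, an actin-bundling protein, averaged 19.1 ± 0.993 against 10.2 ± 1.14 TPM. The log2 fold changes of ARHGAP23 and TAF4 were -0.93 and -0.82. All 12 genes taken in this direction, with NR1D1 and PER2 among them, were lower in every resveratrol library than in every control library. All 12 were among the 40 DESeq2 calls. They were picked for a small p on these same counts, so neither the lack of overlap nor the DESeq2 calls are separate support. Over all genes, groups did not overlap in 12.3%.

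In the higher direction, again with none passing in edgeR, SAT2 averaged 30.5 ± 2.92 TPM in control and 45.8 ± 2.96 TPM in resveratrol. FBP2, a fructose-bisphosphatase of gluconeogenesis, averaged 41.3 ± 1.67 against 62.6 ± 6.56 TPM. LYZ, the lysozyme of myeloid cells, averaged 14.7 ± 2.68 against 28.0 ± 8.82 TPM, and PPA1, a pyrophosphatase, 36.5 ± 3.02 against 53.7 ± 7.95 TPM. The log2 fold changes of TRPM5, AMDHD1 and SCIN were 0.84, 1.16 and 0.67, and TRPM5 passed in DESeq2 (adjusted p = 0.0439). ADAM7, HFM1 and NAALADL1 were low in both groups, with resveratrol means of 0.853, 1.37 and 0.763 TPM. Each of these 12 genes, MSR1 and HSPA5 among them, was higher in every resveratrol library than in every control library. This is no separate support either, since they were picked for a small p.

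The second comparison asked which of the fixed gene lists moved. Camera with the preset correlation called 10 of 30 lists, 7 higher and 3 lower in resveratrol. With an estimated correlation it called 0, with a smallest adjusted p = 0.770, and this was the adjusted p of each of the 10 lists. Fry called 0 lists one-way (smallest adjusted p = 0.493) and 0 mixed (smallest adjusted p = 0.0629). With the replicate number as a block, fry mixed called 4.

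**Figure D2:**
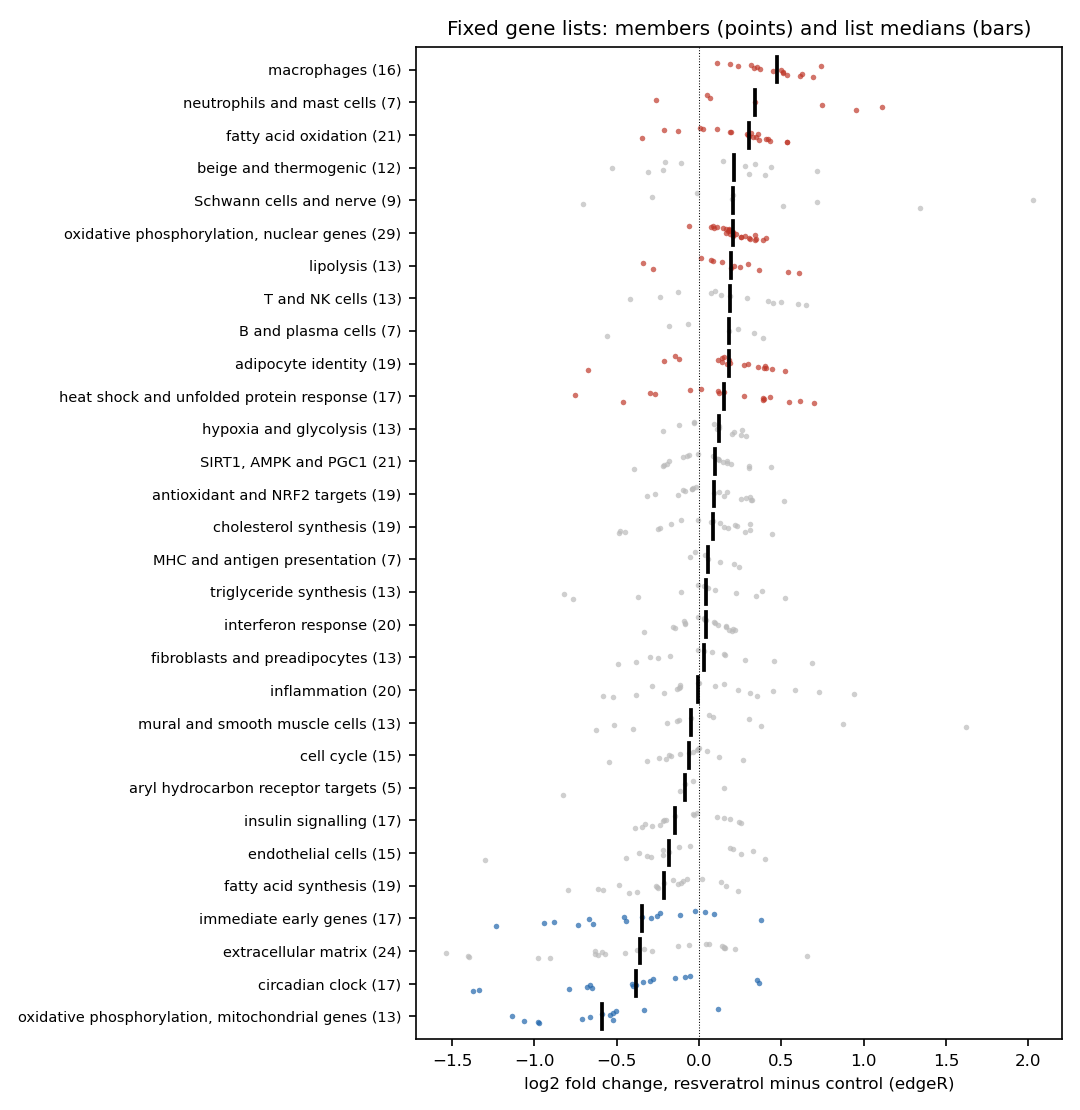
Log2 fold change of each tested member (points) and the median (bars) of 30 gene lists, with the number of tested members in brackets. Lists called higher by camera with the preset correlation are red, those called lower blue and the others grey. Macrophage genes have the highest median, 0.47, and mitochondrially encoded genes the lowest, -0.59.

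Circadian clock genes fell as a list, with a median log2 fold change of -0.38 and 15 of 17 members lower (camera adjusted p = 3.06e-05, and adjusted p = 0.770 with an estimated correlation). In edgeR, 7 of these were lower at an unadjusted p under 0.05, 5 passed when adjusted over the list alone and 0 when adjusted over all genes. DESeq2 adjusted over all genes called NR1D1, PER2 and PER1 (adjusted p = 0.00260, 0.00922 and 0.0159). PER1 averaged 71.2 ± 8.36 TPM in control and 36.6 ± 5.41 TPM in resveratrol, PER2 4.81 ± 0.935 against 1.82 ± 0.719 TPM, and CRY2 40.8 ± 7.59 against 24.5 ± 2.20 TPM (SD, n = 3 each). These 3 genes encode repressors of the CLOCK and BMAL1 complex. BMAL1 itself, named after its value was seen, had a log2 fold change of 0.35. The list's call held without each library.

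Immediate early genes, which cells induce within minutes of a stimulus, fell as a list (median -0.35, 14 of 17 lower, camera adjusted p = 0.0152, and adjusted p = 0.770 with an estimated correlation). NR4A1 averaged 75.2 ± 23.8 TPM in control and 30.6 ± 8.66 TPM in resveratrol, and 1 member passed when adjusted over the list alone. The log2 fold changes of MYC, EGR1 and NR4A2 were -0.74, -0.64 and -0.94. The call was lost without control 1 (median -0.15, adjusted p = 0.292) and without resveratrol 3 (median -0.24, adjusted p = 0.0782), and the median was -0.63 without control 3.

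**Figure D3:**
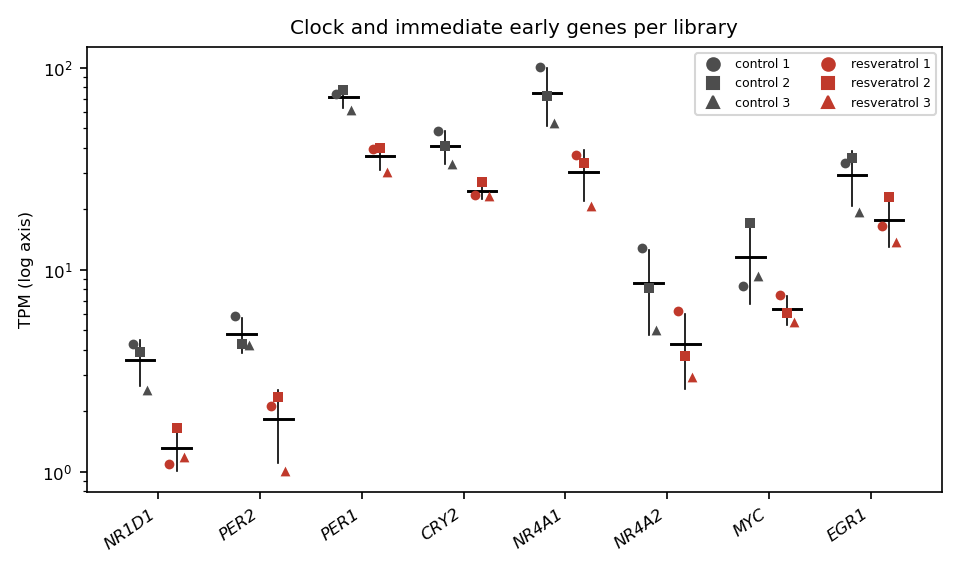
TPM on a log axis of 4 clock and 4 immediate early genes in each library, with control in grey, resveratrol in red, a symbol per replicate number, and the group mean (bar) ± SD (line), n = 3. NR1D1, PER2, PER1, CRY2, NR4A1 and MYC are lower in every resveratrol library than in every control library, and EGR1 and NR4A2 overlap.

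Macrophage genes rose as a list, with all 16 tested members higher, a median of 0.47 and 7 members at an unadjusted p under 0.05 (camera adjusted p = 7.26e-07, and adjusted p = 0.770 with an estimated correlation). None passed when adjusted over the list alone. MSR1, a scavenger receptor, averaged 6.19 ± 1.46 TPM in control and 9.18 ± 0.304 TPM in resveratrol. AIF1 averaged 28.9 ± 6.36 against 41.4 ± 8.92 TPM and TYROBP 105 ± 19.8 against 158 ± 32.4 TPM, and CTSS had a log2 fold change of 0.54. The call held without each library, and the median was 0.25 without resveratrol 1. Genes of neutrophils and mast cells rose as a list of 7 (median 0.34, camera adjusted p = 0.0163, and adjusted p = 0.770 with an estimated correlation). S100A8 averaged 13.1 ± 2.61 against 24.4 ± 2.38 TPM and S100A12 68.8 ± 29.3 against 144 ± 44.2 TPM. MS4A2, a subunit of the IgE receptor of mast cells, averaged 7.99 ± 0.724 against 12.8 ± 3.91 TPM, and the log2 fold change of CSF3R was 0.34. Adjusted over the list alone, 3 members passed. The call was lost without control 2 (median 0.29, adjusted p = 0.0650) and without resveratrol 1 (median 0.39, adjusted p = 0.240). In limma on log2(TPM + 0.5) and log2(TPM + 1) the median was 0.17 and 0.12, still called (adjusted p = 0.00282 and 0.00244).

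Fatty acid oxidation genes rose as a list (median 0.30, 18 of 21 higher, camera adjusted p = 0.00109, and adjusted p = 0.770 with an estimated correlation). SLC25A20, the carnitine carrier of the mitochondrial inner membrane, averaged 57.2 ± 5.67 TPM in control and 78.6 ± 6.71 TPM in resveratrol. ACAA2, ACADM and HADHB, enzymes of beta-oxidation, had log2 fold changes of 0.54, 0.43 and 0.37. CPT1A, the liver form of the entry enzyme, averaged 18.0 ± 3.53 against 13.6 ± 1.67 TPM. The call held without each library, and the median was 0.17 without resveratrol 3 and 0.20 in limma on log2(TPM + 0.5).

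Nuclear genes of oxidative phosphorylation rose as a list, with 28 of 29 members higher and a median of 0.20 (camera adjusted p = 0.00141, and adjusted p = 0.770 with an estimated correlation), but 0 members had an unadjusted p under 0.05. The log2 fold changes of COX7C, NDUFA2 and NDUFA4 were 0.39, 0.34 and 0.35. The call was lost without control 1 (median 0.11, adjusted p = 0.364), control 2 (0.13, 0.0923) and resveratrol 3 (0.07, 0.207), and the median was 0.44 without control 3 and 0.36 without resveratrol 1. Quantile normalization ended it too (median 0.13, adjusted p = 0.0526), and in limma on log2(TPM + 0.5) the median was 0.14. Mitochondrially encoded genes of the same pathway fell as a list, with 12 of 13 lower and a median of -0.59 (camera adjusted p = 5.24e-05, and adjusted p = 0.770 with an estimated correlation). ND1 measured 112, 250 and 101 TPM in control 1, 2 and 3 and 86.5, 74.4 and 55.6 TPM in resveratrol 1, 2 and 3. CYTB measured 812 TPM in control 2 and between 185 and 291 TPM in the other 5 libraries. The log2 fold changes of ND2 and ND3 were -1.06 and -0.52. Without control 2 the median was -0.25, and with array weights in limma it was -0.35, both still called. Mitochondrial genes together took 1.88 ± 0.654% of reads in control and 1.83 ± 0.180% in resveratrol (SD, n = 3 each), and COX1, named after its value was seen, had a log2 fold change of 0.12.

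**Figure D4:**
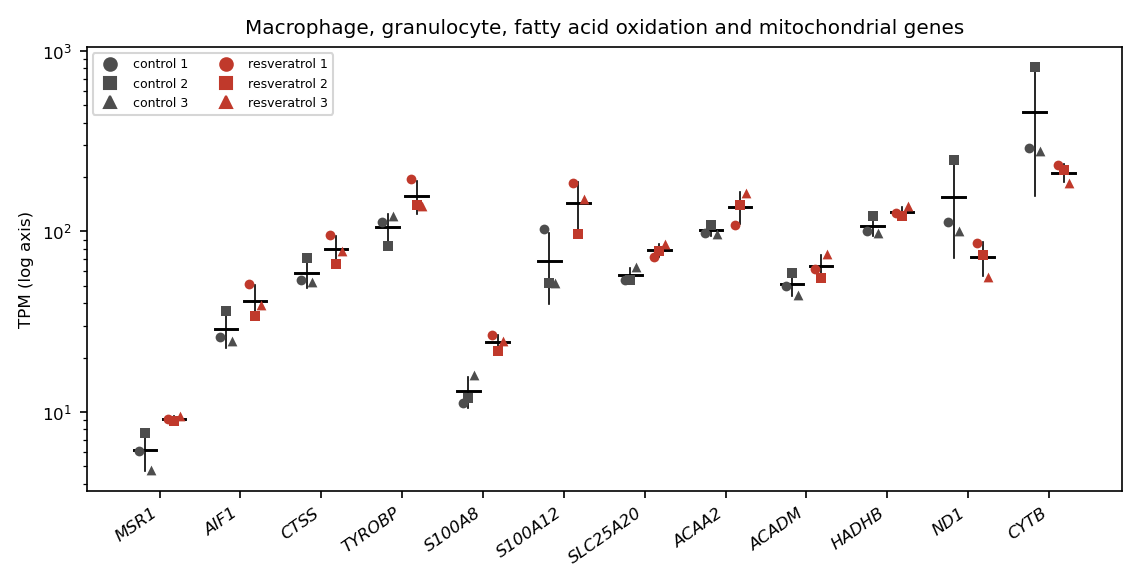
TPM on a log axis of macrophage (MSR1, AIF1, CTSS, TYROBP), granulocyte (S100A8, S100A12), fatty acid oxidation (SLC25A20, ACAA2, ACADM, HADHB) and mitochondrially encoded (ND1, CYTB) genes in each library, with control in grey, resveratrol in red, and the group mean (bar) ± SD (line), n = 3. Control 2 stands above the other libraries in ND1 (250 TPM) and CYTB (812 TPM).

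Adipocyte identity genes rose as a list (median 0.18, 15 of 19 higher, camera adjusted p = 0.0129, and adjusted p = 0.770 with an estimated correlation). ADIPOQ, the adipokine adiponectin, had a log2 fold change of 0.36 (SE 0.21), with every resveratrol library above every control library. GPD1 averaged 388 ± 10.3 against 530 ± 100.5 TPM. LEP, the satiety hormone leptin, averaged 22.3 ± 7.45 against 13.4 ± 6.39 TPM, and the log2 fold changes of RBP4 and ADIRF were 0.45 and 0.41. PPARG and FABP4 had log2 fold changes of 0.28 (SE 0.20) and 0.19 (SE 0.26). The call was lost without control 1 (median 0.17, adjusted p = 0.175), control 2 (median 0.08, adjusted p = 0.282) and resveratrol 3 (median 0.18, adjusted p = 0.0549), and the median was 0.40 without control 3. It was also lost with array weights (median 0.12, adjusted p = 0.0519), quantile normalization (0.11, 0.355) and without the top 20 genes and mitochondrial genes (0.17, 0.0610). Lipolysis genes rose as a list (median 0.19, 11 of 13 higher, camera adjusted p = 0.0450, and adjusted p = 0.770 with an estimated correlation). FFAR4 averaged 10.8 ± 2.99 against 15.2 ± 4.30 TPM. ADRB1 and PRKACA had log2 fold changes of 0.54 and -0.28. The counts of ABHD5 gave a log2 fold change of 0.37 while its TPM averaged 183 ± 41.0 in control and 167 ± 6.34 in resveratrol. The lipases LIPE and PNPLA2 had log2 fold changes of 0.30 (SE 0.25) and 0.14 (SE 0.20). This call held under 9 of 19 alternatives and was lost without control 1 (median 0.16, adjusted p = 0.224), control 2 (0.17, 0.308), resveratrol 2 (0.25, 0.140) and resveratrol 3 (0.15, 0.0782). It was also lost in limma on log2 TPM (median 0.05, adjusted p from 0.180 to 0.210 over 3 pseudocounts), with array weights (median 0.05, adjusted p = 0.273), with quantile normalization (median 0.09, adjusted p = 0.427) and without the top 20 genes and mitochondrial genes (median 0.20, adjusted p = 0.0546).

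Genes of the heat shock and unfolded protein response rose as a list (median 0.15, 12 of 17 higher, camera adjusted p = 0.0430, and adjusted p = 0.770 with an estimated correlation). HSPA5, HERPUD1 and TRIB3, targets of endoplasmic reticulum stress, had log2 fold changes of 0.70, 0.55 and 0.61. BAG3, a target of the cytosolic heat shock factor, had one of -0.46. The call was lost without control 1 (median -0.03, adjusted p = 0.365), control 2 (median 0.23, adjusted p = 0.0587) and resveratrol 3 (median 0.09, adjusted p = 0.124). It was also lost with quantile normalization (median 0.08, adjusted p = 0.246), library totals alone (0.21, 0.0574) and without the top 20 genes and mitochondrial genes (0.16, 0.0546). The median was 0.08 in limma on log2(TPM + 0.5), 0.26 with array weights and 0.25 without resveratrol 1.

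Extracellular matrix genes had a median of -0.36, with 16 of 24 lower, and were not called (camera adjusted p = 0.0574), although 10 of 19 alternatives called them lower. CCN2 averaged 102 ± 30.4 TPM in control and 52.4 ± 10.1 TPM in resveratrol, and THBS1 207 ± 107 against 100.05 ± 20.4 TPM. Tendon and cartilage genes stood high in the same library as many of its members. TNMD measured 37.1 TPM in control 1 and at most 2.70 TPM elsewhere, and COMP measured 43.2 TPM in control 1 and 10.4 TPM in control 3. COL2A1, the collagen of cartilage, measured 11.8, 5.08 and 7.26 TPM in control 1, 2 and 3 and 0.936, 0.970 and 1.08 TPM in resveratrol 1, 2 and 3. These 3 genes are named after their values were seen. Without control 1 the matrix list had a median of -0.01 (adjusted p = 0.928), and without control 2 (median -0.57, adjusted p = 0.00592), control 3 (0.0219) or resveratrol 2 (0.0168) it was called. It was also called in limma on log2 TPM with pseudocounts of 0.5, 1 and 0.1 (adjusted p = 0.0214, 0.0140 and 0.0308), with array weights (2.39e-04), quantile normalization (3.34e-04), a mean of at least 1 TPM (0.0443) and library totals alone (0.0177).

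The remaining lists of metabolic and signalling pathways were not called on all 6 libraries. The SIRT1, AMPK and PGC1 list had a median of 0.10 (camera adjusted p = 0.430), which was -0.02 without control 2, 0.03 without resveratrol 3 and 0.0035 in limma on log2(TPM + 0.5). SIRT1 averaged 8.28 ± 2.52 TPM in control and 6.66 ± 0.272 TPM in resveratrol. The kinase subunits PRKAA1, PRKAA2, PRKAG1 and PRKAG2 had log2 fold changes of -0.07, -0.10, 0.30 and -0.40. PPARGC1A lay below the filter, with 5 to 25 reads per library. Fatty acid synthesis had a median of -0.22 with 15 of 19 lower (camera adjusted p = 0.430), and FASN and SCD had log2 fold changes of -0.08 (SE 0.45) and -0.16 (SE 0.60), SREBF1 and FADS2 of -0.42 and -0.38. Without control 1 this list was called lower (median -0.53, adjusted p = 8.76e-04), and its median was 0.05 without control 3 and -0.01 without resveratrol 1. Triglyceride synthesis had a median of 0.04, a mean of -0.03 and PNPLA3 at -0.77, and its median was -0.02 in limma on log2(TPM + 0.5). Without control 1, control 2 or resveratrol 2 that median was 0.01, 0.02 and 0.03, and camera's direction was down. Antioxidant and NRF2 targets had a median of 0.09, with SOD1 at 0.51 and HMOX1 at 0.31, and were called higher without control 3 (median 0.21, adjusted p = 0.0345) and without resveratrol 1 (median 0.10, adjusted p = 0.0299). Their median was -0.08 without control 2 (adjusted p = 0.972) and -0.05 with array weights. Beige and thermogenic genes had a median of 0.21, with GATM at 0.40 and UCP3 at 0.30, and aryl hydrocarbon receptor targets one of -0.09, with AHRR at -0.82 and AHR at -0.12. Insulin signalling had a median of -0.15, with PTPN1 at -0.39 and IGF1 at -0.35, cholesterol synthesis one of 0.09, with NSDHL at 0.44, and hypoxia and glycolysis one of 0.12, with VEGFA at 0.28 and PFKFB4 at 0.25. With 1 library left out, the insulin signalling median moved to -0.05 without control 3, -0.07 without control 2 and -0.09 without resveratrol 1. Over such fits the medians lay between 0.02 (without resveratrol 1) and 0.14 (without control 3) for cholesterol synthesis and between 0.02 (without resveratrol 3) and 0.19 (without resveratrol 1) for hypoxia and glycolysis. They lay between -0.20 (without resveratrol 3) and -0.03 (without resveratrol 2) for aryl hydrocarbon receptor targets and between 0.11 (without resveratrol 2) and 0.19 (without control 3) for beige and thermogenic genes.

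Other cell types and immune pathways were not called on all 6 libraries either. Medians were 0.19 for T and NK cells (CD2 0.65, KLRK1 0.60), 0.18 for B and plasma cells (XBP1 0.39, TNFRSF17 -0.56) and 0.21 for Schwann cells and nerve (CDH19 0.51). They were -0.18 for endothelial cells (PROX1 -1.30, TEK 0.40), 0.03 for fibroblasts and preadipocytes (ZNF423 -0.49, MFAP5 0.69) and -0.06 for the cell cycle (UBE2C -0.55, TPX2 -0.31). Interferon response had a median of 0.04 (IFIT2 -0.34, STAT2 0.20) and antigen presentation one of 0.06 (PSMB9 0.24, CD74 0.21). Mural and smooth muscle cells had a median of -0.05 and a mean of 0.10, with PDGFRB at -0.63 and CSPG4 at -0.40. For inflammation the mean was 0.07 while camera's direction was down (adjusted p = 0.994), with LCN2 at -0.52 and VCAM1 at 0.35. Fewer than 5 members were tested for skeletal muscle (TPM2 0.21, PYGM -0.12), skin (DSP -0.17, KRT10 0.02), erythroid cells (ALAS2 0.34, HBB 0.32) and sex-linked genes. Values in brackets after gene names are log2 fold changes. With a library left out, T and NK cells were called higher without resveratrol 2 (median 0.37, adjusted p = 0.0162) and resveratrol 3 (0.42, 0.0472), with a median of -0.26 without resveratrol 1. Schwann cells were called higher without resveratrol 3 (0.37, 0.00524), with a median of -0.04 without resveratrol 1. Interferon response was called higher without control 2 (0.21, 0.0456) and resveratrol 2 (0.16, 0.0196), with a median of -0.09 without control 1 and -0.02 without resveratrol 1. Mural cells were called lower without resveratrol 2 (-0.31, 0.0146), and camera's direction was up without resveratrol 3 (median 0.0045). The cell cycle median was 0.15 without control 2, 0.07 without resveratrol 3 and -0.24 without resveratrol 2, and that of fibroblasts and preadipocytes -0.09 without control 3 and -0.06 without resveratrol 1. The median was -0.08 without resveratrol 1 for antigen presentation, 0.03 without control 1 for B and plasma cells, -0.11 without control 3 for endothelial cells, and from -0.18 (without resveratrol 1) to 0.11 (without resveratrol 2) for inflammation. In limma on log2(TPM + 0.5) the medians of interferon response, antigen presentation and fibroblasts were below 0, at -0.03, -0.02 and -0.04, and that of T and NK cells was 0.03. The median over all genes was -0.079 in that fit, against -0.0075 in edgeR, and camera's direction for these lists stayed up. The Y-linked genes EIF1AY and KDM5D had reads in all 6 libraries, from 279 to 661 and from 488 to 912.

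The third comparison concerned the assembled loci, since the study's title is about lncRNAs. None of the lncRNAs in the fixed list was found by symbol among the tested rows, so no named lncRNA is reported. Assembled loci took 20.7 ± 3.70% of reads in control and 16.5 ± 1.96% in resveratrol (SD, n = 3 each). MSTRG.14710 alone took 13.8%, 6.92% and 17.6% of reads in control 1, 2 and 3. In resveratrol 1, 2 and 3 it took 9.003%, 11.7% and 8.38%. The summed shares therefore lean on 1 locus and do not by themselves show a fall across the assembled loci. Of 381 tested, edgeR called 0 at an adjusted p under 0.05 over all genes, and 34 had an unadjusted p under 0.05 (8.92%, against 6.53% of all genes), 10 higher and 24 lower. Groups did not overlap in 25 of them (6.56%, where chance gives 10%, against 12.3% of all genes). DESeq2 called 3. Adjusted over the assembled loci alone, 1 locus passed. This was MSTRG.13223, at 34.8, 37.7 and 25.5 TPM in control 1, 2 and 3 and 10.3, 12.1 and 6.87 TPM in resveratrol 1, 2 and 3, with a log2 fold change of -1.66 (SE 0.26) and an edgeR adjusted p over these loci of 0.0313. MSTRG.9374 averaged 2.77 ± 1.36 TPM in control and 10.1 ± 5.10 TPM in resveratrol. The log2 fold changes of MSTRG.2752, MSTRG.6296 and MSTRG.9710 were 0.58, 0.52 and 0.50, and those of MSTRG.14191, MSTRG.13318 and MSTRG.2087 were -0.70, -1.22 and -0.55. As a set, 265 of the 381 were lower, with a median of -0.29 and a camera p of 1.81e-04 with the preset correlation, a test chosen after seeing the data. The p was 0.314 with an estimated correlation, and without control 2 the median was -0.08 (camera p = 0.106 with the preset correlation).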

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

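Added after the data were seen were limma on log2(TPM + 0.5), the fits with other scaling or without robust, and DESeq2 with a library left out. The count of 0 genes in edgeR became 1 in limma without trend and robust, 2 with array weights, 1 after quantile normalization and 40 in DESeq2. Each of these limma fits called ENSSSCG00000011856.3, named after its value was seen, which was not among the 40 in DESeq2. Array weights added COL2A1, which DESeq2 called too. In limma on log2(TPM + 0.5), the test first planned, the smallest adjusted p was 0.0561, against 0.409 in edgeR. Leaving out a library gave 0 to 5 in edgeR, with 5 without control 2. DESeq2 gave 41, 197 and 91 without control 1, 2 and 3, and 21, 43 and 19 without resveratrol 1, 2 and 3. These shared 13, 35, 29, 8, 28 and 14 genes with the 40. Assembled loci went from 0 to 3 in DESeq2. The 205 genes past an unadjusted p of 0.05 and a 2-fold change became 118 with limma on log2(TPM + 0.5), 80 with log2(TPM + 1), 122 without trend and robust, 100 after quantile normalization and 388 with no filter, which tested more genes. With 1 library left out the range was 146 (without resveratrol 3) to 323 (without control 3). The 10 lists became 6 without the top 20 genes and mitochondrial genes, where the mitochondrial list has no members, and 0 with camera's estimated correlation, fry one-way and fry mixed. Leaving out a library gave 6 (without control 1) to 13 (without resveratrol 2). The cause of the other changes was not tested.

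Macrophages, circadian clock and fatty acid oxidation were called under all 19 alternatives that used camera's preset correlation, and the mitochondrial list under its 18. All of these used the preset of 0.01, while the estimated correlations of these lists were 0.443, 0.149, 0.315 and 0.776, in the same order. None of the 126 named genes passed the adjusted threshold in the main fit. Of their 2632 alternative values, 18 passed it and 2614 again did not, which says nothing about the size of the effects. A change of sign with both values larger than their own SE was found in 0. Smaller changes of sign were not counted. The replicate block left the genes at 0, moved the 205 to 185 and kept 10 lists, while fry mixed went from 0 to 4. The numbers are not stated to pair the samples. Residuals of libraries with the same number correlated at 0.157, 0.0741 and 0.200, and every library correlated best with its own number, a hint from the data only. The test of lncRNAs with their neighbours, at any distance, was not run. At these depths, this spread and 3 libraries per group, 8.96% of simulated 1.5-fold changes were recovered.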

Other observations

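Chosen after their results were seen were the tests of a single library, of control 1 and of control 2 alone, of the HOX genes, of the DESeq2 splits, and of the splits for genes at an unadjusted p under 0.05. All genes in the next sentences were also picked after their values were seen. NFATC1, a calcium-regulated transcription factor, averaged 10.4 ± 2.93 TPM in control and 4.15 ± 1.22 TPM in resveratrol, NFATC2 5.86 ± 3.29 against 1.66 ± 0.427 TPM, and RCAN1, an inhibitor of calcineurin, 40.5 ± 9.12 against 20.4 ± 4.82 TPM (SD, n = 3 each). All 3 were among the 40 DESeq2 calls, and none passed in edgeR on all 6 libraries. NFATC2 passed in edgeR without control 2 (log2 fold change -2.20, adjusted p = 0.0393). MT1X, a metallothionein that binds zinc, averaged 423 ± 40.4 against 189 ± 48.2 TPM, with no overlap between the groups.

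The clock list was called lower under every alternative with camera's preset correlation. Its median without 1 library was at most -0.36, which argues against a single library making the fall. The bounds for this reading were set after the values were seen. A shift of the clock's phase, as another time of tissue collection would give, stays open. All 5 of 5 clock outputs not looked at before had a negative log2 fold change, with a median of -0.30. A fall of the clock from another cause could lower these outputs too, so they do not set a phase shift apart. Only WEE1 and USP2 had an unadjusted p under 0.05, and KLF9 lay within its error of 0 (-0.08, SE 0.25). USP2 was highest in control 1 (2.16 TPM), and control 2 (0.609 TPM) lay below resveratrol 2 (0.665 TPM). A weaker glucocorticoid or handling response stays open too, on few genes. Of 8 targets fixed beforehand 5 were tested, and 4 of these 5 had a negative log2 fold change. Of these 4, 1 (ERRFI1) had an unadjusted p under 0.05. The median of -0.21, only just past the bound of -0.2 set beforehand, is that of CEBPD, with an SE of 0.42. An effect of the diet on the clock stays open and was not tested apart from these, since collection times are not given in the sources used here.

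Of 11 tendon and cartilage markers picked after their values were seen, all 11 had a negative log2 fold change (median -3.77) and stood highest in control 1, and some were high in control 3 too, such as COL11A2 at 13.8 TPM and CILP2 at 8.76 TPM against at most 0.124 and 0.243 TPM in resveratrol. Of 9 tested tendon and cartilage markers not looked at before, 8 had a negative log2 fold change, 2 of them at an unadjusted p under 0.05. CHAD, 1 of those 2, was also among the 40 DESeq2 calls, so it counts less as a marker not looked at before. MATN4 went the other way, with a log2 fold change of 1.02 (unadjusted p = 0.00898, the smallest of the 9), and ASPN and OGN were highest in control 2, at 67.8 and 80.6 TPM. Connective tissue of another kind in control 1 is a candidate source for part of this, with control 3 not tested: 66.7% of these 9 were at least 1 log2 unit higher in control 1 than the mean of the other 5 libraries, against 3.25% of all genes, and THBS4 reached 192 TPM and FMOD 222 TPM in control 1. Without control 1 the matrix list's median was -0.0077, but COL2A1 and HOXA10 were higher in all 3 control libraries and COL11A2 and CILP2 in control 1 and 3, which control 1 alone would not give. Another position of the depot along the body stays open: 4 of 18 HOX genes had an unadjusted p under 0.05 in either direction, all lower, where 1.17 were expected (one-sided exact hypergeometric p = 0.0264, across genes that are not independent), but their values had been seen before the test, which therefore decides nothing.

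Mitochondrially encoded genes were highest in control 2, the shallowest library. Thinning all libraries to its total left the median at -0.591, but thinning keeps each gene's share of the reads on average and so does not test depth, which stays open. Whether control 2 alone makes the pattern cannot be told apart from a diet effect: without it the median was -0.25, between the bounds set, after the result was seen, for either answer.

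Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The 205 genes past an unadjusted p of 0.05 and a 2-fold change compare with 208 in the highest other split, and 2 splits reached the real value. The 973 genes at an unadjusted p under 0.05 compare with 1082, and 4 splits, the real one included, reached 973. The 10 called lists compare with 5 to 11 in the other splits, and 3 splits, the real one included, reached 10. For genes and for assembled loci in edgeR the real and the highest other value were both 0, in all 10 splits. DESeq2's 40 genes compare with 101 when control 1, control 2 and resveratrol 1 are set against the rest, and 2 splits reached 40, a check added once the 40 were known.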
